A study of Mus musculus with 4 samples.

How the data were processed

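RNA and surface proteins were counted in the same single cells (CITE-seq, in which antibodies carry DNA barcodes that are read beside the RNA) in 4 libraries of sorted mouse ankle synovial cells. Per the labels' protocols, live CD45-positive CD11b-positive cells without Ly6G, SiglecF, CD64, MHC class II, Ly6C and CD177 were sorted, and the libraries were made with 10x Genomics 3' chemistry. Each stage of serum-transfer arthritis had 1 library, taken on day 0 for baseline, on day 7 for peak, on day 14 for plateau and on day 56 for resolution. How many mice went into each library is not given in the sources used here. The titles of the 3 arthritis samples carry the tag "Clo-lip", which the baseline title lacks and which no other label explains. The tag cannot be told apart from the stage.

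The deposited matrices hold raw UMI counts, not normalized, for 32285 genes and 92 antibodies in each cell barcode. Per the file headers and the submitters' processing notes they were made with Cell Ranger 6.1.2 and the mm10 build, and the notes also list Seurat 4.4.0 without saying for which step. A cell filter beyond Cell Ranger's own is not given in the sources used here. The list of antibody barcodes was read for names alone and gave no measurement.

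Cell filters, gene lists, cell type markers, comparisons, tests and the rule for naming genes were fixed before the data were examined. Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept. From baseline to resolution, the gene minimum removed 19, 167, 65 and 43 barcodes and the mitochondrial limit removed 38, 382, 211 and 125 more. Scrublet, run on each library through scanpy 1.11.5, called 5, 0, 3 and 0 doublets, which were removed. With so few calls, its automatic thresholds were not usable on these libraries. Removing the 6% of cells with the highest doublet scores in each library, and removing cells with at least 10 UMIs of both CD45 antibodies, were therefore added after seeing the data.

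Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components and 15 neighbours went into Leiden clustering at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9). The antibodies were left out of the clustering and the libraries were not integrated. The 28 clusters were named from markers of 22 cell types. A name needed at least 3 markers, and at least 50% of the type's markers. Each had to be detected in at least 10% of the cluster's cells, with at least 2 times its share of UMIs in other cells. The type also needed more such markers than any other type. No other type could have more markers among the cluster's 10 leading genes, and a cluster of low depth needed a marker of the type there. Names are written with "-like" because they rest on RNA markers. Clusters named nonclassical monocyte-like, classical monocyte-like or macrophage-like (clusters 2, 3, 5, 6, 7, 11 and 18) form the monocyte-lineage class.

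With 1 library per stage no test between stages was possible. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals, and summed UMI counts of the class, given as CPM (UMIs of a gene scaled to the library's total), have exact 95% Poisson intervals. Where a share is 0, the upper limit is 3 counts of the total. Intervals and limits cover counting error alone, not differences between mice or libraries. Stage contrasts are log2 ratios of CPM with 0.5 counts added. For each of 26 gene lists, the median log2 ratio of the detected members was set against 10000 random lists of as many genes, matched on mean expression in 20 bins. A list is called higher or lower when it lies outside the central 95% of the random lists, which describes these libraries and is no test of stage. This step was tested on simulated data: with no shift 2% of 100 lists lay above the range, and with a log2 shift of 0.5 or 1 all 100 did. The simulated libraries differed by counting error alone, apart from the shifted genes. These rates therefore do not carry over to the real libraries, where random lists spread more widely.

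Named genes of a stage contrast are the 12 highest and 12 lowest ratios (6 and 6 for resolution against baseline) among genes with at least 50 CPM in the higher library and at least 30 UMIs. Mitochondrial, ribosomal, haemoglobin, sex-linked, immunoglobulin and T cell receptor genes and unnamed gene models were left out of the naming. From each list, the members with the largest change and the highest mean were also named, as were the genes of the sorting markers. The median log2 ratio of all detected genes was -0.33 for peak against baseline, 0.44 for plateau against peak, 0.03 for resolution against plateau and 0.21 for resolution against baseline, with totals of all UMIs as the scale. With edgeR's TMM totals these medians were -0.019, 0.042, -0.030 and 0.060. Of the lists called higher or lower, the lysosome list at plateau against peak moved from 0.40 to just below 0 under TMM and stayed above its random lists, and endothelial genes at resolution against baseline lost their call under TMM and DESeq2's size factors. No other called list and no named gene changed sign or call under these 2 scalings.

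Origin was read from r, the log2 ratio of CD45.1 to CD45.2 antibody UMIs with 1 added to each. A Gaussian mixture of 2 components was fitted to r in each library (scikit-learn 1.9.0), and cells with a posterior of at least 0.95 were assigned. The mixture left 6.85%, 8.16%, 27.4% and 13.7% of cells unassigned from baseline to resolution. At peak and plateau, 30.6% and 48.4% of the cells it called CD45.2 had fewer than 3 CD45.2 UMIs, against 7.37% and 1.23% within the monocyte-lineage class. Values under fixed rules (r at least 1 or at most -1, and at least 2 or at most -2) are therefore given beside the mixture's for all cells and for some clusters and stages.

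CD45.1 and CD45.2 cells of the class were summed within each library (at least 20 cells per sum), which gave 8 sums. They were compared with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr) in R 4.3.3, with the library as a block since both sums of a library come from the same suspension. The 4 stages stand as the replicates, so the spread includes differences between stages. P values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. The named genes are the 15 highest and 15 lowest fold changes among those past the threshold with the same sign in all 4 libraries. Lists were tested with camera (preset correlation 0.01, and an estimated correlation) and fry from limma 3.58.1. Antibodies were tested in the same way, without the CD45.1 and CD45.2 antibodies. The panel has no isotype controls, which had been planned as the background, so the CD3 antibody stands in for them. The RNA step was tested on simulated data with 200 changed genes among 8895: it recovered 4.48% of genes changed 1.5-fold, 67.2% at 2-fold and 90.9% at 4-fold, and 4 of 112 calls were genes that had not been changed. The CD45.1 share of each cluster was compared with the other cells of the same library by an exact two-sided sign-flip permutation test over 4 libraries, whose smallest possible p is 0.125.

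The alternatives fixed beforehand were other cell filters (500 genes, 5% mitochondrial UMIs), doublets kept, Leiden resolutions of 0.4 and 1.2, other scalings, 5 counts added, equal weight to each cell or cluster, cells thinned to 2000 UMIs, all retained cells, no filter on low counts, DESeq2 1.42.0, no replicate block, each library left out, and cells matched by cluster. Equal weight to each cluster averages the CPM of the class's clusters with at least 20 cells in both libraries, whatever their size. Cluster 7 (16 cells at peak, 13 at plateau) thus entered only resolution against baseline. Cluster 6 (15 at baseline) was left out of contrasts with baseline, and cluster 18 (14 at plateau) of those with plateau. Antibodies with no UMIs at baseline (5 of the panel, among them CXCR5, CD68, P2Ry12 and TLR4) were left out of the naming in all stage contrasts. This includes contrasts without baseline, although P2Ry12, for example, had 1.86 UMIs per cell of the class at peak and 0.560 at plateau. These antibodies were kept in the test between origins, where the other 3 libraries carry them. Another 5 with at most 50 UMIs anywhere (CD40, CD45, P2X7R, Podoplanin and SiglecH) are not described. Gene positions came from the GRCm38.p6 annotation, the same build as mm10. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.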

Results

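Myeloid cells sorted from mouse ankle synovium were profiled for RNA and surface proteins at 4 stages of arthritis induced by serum of K/BxN mice, which carries joint-directed autoantibodies. The mice were bone marrow chimeras: recipients with CD45.2 had received CD45.1 marrow while the ankle was shielded from irradiation, so the CD45 variant on a cell tells marrow-derived donor cells from recipient cells. There was 1 library per stage. Baseline, peak, plateau and resolution held 1128, 6490, 3104 and 4779 cell barcodes, with 12015315, 59816482, 30781729 and 27250421 gene UMIs and 2214675, 6723223, 2684149 and 2387955 antibody UMIs. After filtering, 1066, 5941, 2825 and 4611 cells were kept. Their median depths were 7751, 8250, 6783 and 4912 gene UMIs and 966.5, 806, 629 and 365 antibody UMIs per cell. As no stage had a replicate, stages are compared by size alone, and all intervals are 95% intervals of counting error.

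Which kinds of cells made up the sort at each stage was compared first. Nonclassical monocyte-like cells, the kind that patrols vessels in blood, were 57.4% of cells at baseline (54.4 to 60.4), 3.45% at peak (3 to 3.95), 3.08% at plateau (2.47 to 3.79) and 28.2% at resolution (26.9 to 29.5). They fell into cluster 7, with 20.4%, 0.269%, 0.460% and 11.4% of cells, and cluster 3, with 37.1%, 3.18%, 2.62% and 16.8%, whose name depends on the clustering: 82.7% of its cells lay in a classical monocyte-like cluster at resolution 0.4 and 81.6% in an unnamed one at resolution 1.2. Ly6c2, a gene of classical monocytes, had 599, 357, 589 and 494 CPM in cluster 3 and 62.7, 76.1, 257 and 57.7 CPM in cluster 7 (4 and 12 counts at peak and plateau). Classical monocyte-like cells, the kind that blood sends into inflamed tissue, were 3.56% (2.53 to 4.86), 28.2% (27.1 to 29.4), 6.41% (5.53 to 7.37) and 1.13% (0.843 to 1.48). Macrophage-like cells were 17.4% (15.1 to 19.8), 1.60% (1.30 to 1.95), 4.28% (3.57 to 5.10) and 35.4% (34.0 to 36.8). Together the cells with these names, the monocyte-lineage class, were 78.3% of the sort at baseline (75.7 to 80.8), 33.2% at peak (32.0 to 34.5), 13.8% at plateau (12.5 to 15.1) and 64.7% at resolution (63.3 to 66.1). Osteoclast-like cells, with the markers of bone-resorbing cells, were 3.69% at peak (3.22 to 4.20), 13.7% at plateau (12.4 to 15) and 0.672% at resolution (0.457 to 0.953). None were found among 1066 cells at baseline, which allows a share of up to 0.281%.

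Cells of other types were present too. Neutrophil-like cells were 5.44% at baseline (4.16 to 6.98), 0.623% at peak (0.439 to 0.857), 0.142% at plateau (0.0386 to 0.362) and 0.152% at resolution (0.0611 to 0.313). Type 2 dendritic-like cells, which present antigen, were 0.750% (0.325 to 1.47), 2.51% (2.13 to 2.94), 1.24% (0.864 to 1.72) and 2.26% (1.85 to 2.73). Basophil-like cells were 1.06% at peak (0.816 to 1.35). At the other stages they were not detected, which allows up to 0.281% at baseline, 0.106% at plateau and 0.0651% at resolution. NK-like cells were 1.59% at baseline (0.932 to 2.54) and at most 0.390% at the other stages, and B-like, mast-like and endothelial-like cells stayed under 0.5% at every stage. Clusters without a name held 8.54%, 55.6%, 65.5% and 26.2% of cells. The largest of them were led by Cxcl3 and Cxcl2 (cluster 0), by Aif1 and Apoe (cluster 1) and by Spp1 and Arg1 (cluster 4), so the named types leave out part of the cells at peak and plateau. With the unnamed clusters 0, 1, 4, 9 and 10 added, the class held 865 of 1066 cells at baseline and 4880 of 5941 at peak. It then held 1924 of 2825 at plateau and 4047 of 4611 at resolution. The low class share at peak and plateau thus depends on which clusters the rule named. At the finer clustering of resolution 1.2 the monocyte-lineage share was 48.1%, 28.9%, 11% and 49.4%.

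**Figure D1:**
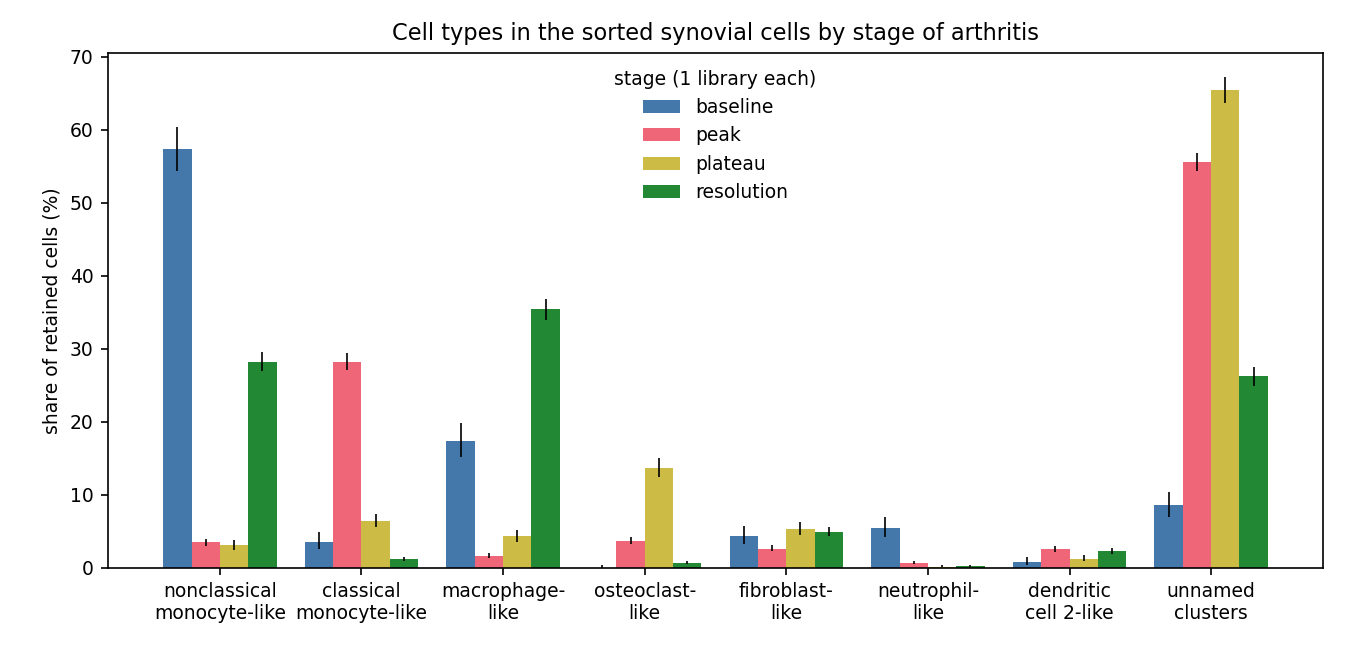
Share of retained cells (%, vertical axis) of each cell type at each stage, with exact 95% binomial intervals and 1 library per stage. Nonclassical monocyte-like cells stood at 57.4% at baseline and 28.2% at resolution, classical monocyte-like cells at 28.2% at peak, and osteoclast-like cells at 13.7% at plateau.

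The comparison of peak with baseline asks what monocyte-lineage cells expressed when joint swelling was greatest. It rests on 18982155 UMIs of 1975 cells at peak and 7590948 UMIs of 835 cells at baseline. Interferon response genes, which cells switch on in answer to interferons and viruses, were higher at peak in 25 of 25 detected members, with a median log2 ratio of 1.73. Among them Isg15 was 9.84-fold higher (1480 against 150.3 CPM, interval of the ratio 9.28 to 10.5) and Cxcl10, a chemokine for T cells, 14.2-fold higher (829 against 58.5 CPM, 12.9 to 15.6). Inflammatory cytokines and chemokines were higher in 17 of 22 members, with a median of 0.84, or 0.68 with members at 0 counts set to 3 counts. Il1b, a fever-inducing cytokine, was 2.43-fold higher (2749 against 1130 CPM, 2.38 to 2.49). Hypoxia and glycolysis genes were higher in 16 of 17 members (median 0.76), with Hif1a, an oxygen-sensing transcription factor, 3.45-fold higher (402 against 116.5 CPM) and the glucose transporter gene Slc2a1 4.31-fold higher (65.8 against 15.3 CPM). Genes of MHC class II and antigen presentation were higher in 12 of 14 members (median 0.57), with H2-Eb1 2.02-fold higher (397 against 197 CPM).

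Of single genes, the largest ratios at peak were those of Timp1, an inhibitor of matrix proteases, 132-fold higher (104 against 0.790 CPM, 60.6 to 360), and Lrg1, 95.4-fold higher (75.4 against 0.790 CPM, 43.7 to 260.5). Dmkn, Ifitm1, Spp1, Ly6a, Ifit1bl1, Arg1, Igfbp6, Slfn4, Mmp19 and Ifit1 followed, between 56.4-fold and 16.3-fold higher. Free RNA taken up by all droplets would put a gene at a similar level in other cell types. In the 102 B-like, NK-like, basophil-like and mast-like cells at peak, with a median depth of 3749 UMIs against 8508 in the class, Lrg1 (1.80 CPM), Mmp19 (55.7 against 156), Cxcl10 (187 against 829) and Isg15 (481 against 1480) stood lower than in the class. Timp1 (98.8), Ifit1bl1 (82.6 against 93.5), Spp1 (1110), Arg1 (95.2), Ly6a (374) and Ifitm1 (5280 against 367) did not stand clearly lower there, which decides nothing, since these cells, 63 of them basophil-like, can express such genes themselves. The same holds for Hist1h1e, Csnk2a2 and Mbd2 at peak, for Tnf, Abhd2, Csnk2a2 and Cd72 at resolution, and for Cd81, Isg15, Il1rn and Lmnb1 at plateau, where there were only 9 such cells. The largest ratios at baseline were those of Retnla, an alternative-activation gene, 30.8-fold higher there than at peak (261.5 against 8.48 CPM), and of Fabp4, a fatty acid carrier, 30.2-fold higher. Fxyd2, G0s2, Lyve1, Pf4, Gpr34, Eno3, Sparc, Vsig4, Aqp1 and Alox5 followed, between 19.5-fold and 8.28-fold. Fcgr1, which encodes the CD64 that the sort excluded, was 7.58-fold higher at peak (446 against 58.9 CPM).

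Some lists of this contrast hold the genes that name the clusters. These lists went with the cell shares: nonclassical monocyte genes were lower at peak in 15 of 15 members (median -2.12), tissue macrophage genes in 16 of 18 (-2.01), and classical monocyte genes were higher in 11 of 12 (0.78). With equal weight to each cluster the first 2 lost their call (-0.29 and -0.05), as did mast cell genes (0.21), while classical monocyte (0.29) and interferon genes (0.51) stayed above the random lists. This weighting leaves out clusters with fewer than 20 cells in either library, here cluster 6 (15 cells at baseline) and cluster 7 (16 at peak). The same weighting put 4 lists without a call above the random lists, NF-kB feedback (0.30), immune complex receptors (0.46), regulatory (0.53) and lysosome genes (0.37). Osteoclast genes were higher in 6 of 6 members (median 2.05, or 1.68 with floors). But Ctsk, the collagen-degrading cathepsin K, stood at 116 CPM in the class and at 242.5 in the other cell types, and Acp5 at 63.1 and 115. Free RNA is thus left open for both, and the other members were not set against those cells. Neutrophil genes were lower (median -1.15), with 4 of 14 members higher. Fibroblast genes (median 1.74, or 1.34 with floors, 7 of 9 higher) and mast cell genes (0.63, or 0.12 with floors, 5 of 6 higher, 5 members under 30 counts) were higher too. No call was made for NF-kB feedback genes (-0.19), immune complex and complement receptors (0.26), regulatory and repair genes (-0.06, or -0.22 with floors), lysosome and lipid genes (0.05), cell cycle (-0.52), adhesion and trafficking (-0.18), dissociation stress (-0.21) and oxidative phosphorylation (0.03). Nor was there one for NK cell (-0.71, or 0.36 with floors), T cell (-0.96, or -1.14), B cell (-0.18, or -0.81), erythroid (-1.68 either way), endothelial (-0.97, or 0.60), conventional dendritic cell (-0.31, or -0.23) and platelet genes (-2.06, or -1.79), most of which have members under 30 counts.

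From peak to plateau, which asks what set the sustained stage apart, tissue macrophage genes were higher in 17 of 18 members (median log2 ratio 2.10). C1qc, a subunit of the first complement component, was 7.31-fold higher (1110 against 152 CPM, 6.94 to 7.70), Pf4, a chemokine of resident macrophages and platelets, 9.24-fold (670.2 against 72.5 CPM, 8.61 to 9.92) and the complement receptor gene Vsig4 8.63-fold (209 against 24.2 CPM). Regulatory and repair genes were higher in 17 of 22 members (median 0.77, or 0.75 with floors), among them Gas6, a bridge for the uptake of dying cells, 5.05-fold higher (80.5 against 15.96 CPM, 4.21 to 6.03). Lysosome and lipid genes were higher in 15 of 21 (0.40, or just below 0 with TMM totals, above the random lists either way), with Cd63, a lysosomal tetraspanin, 4.55-fold higher (411 against 90.4 CPM). Interferon response genes were lower in 24 of 25 members (median -0.95): Isg15 was 3.77-fold lower (392 against 1480 CPM) and Cxcl10 2.38-fold lower (349 against 829 CPM).

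The named genes of this contrast were Aqp1 (11.1-fold), Fxyd2, Crip2, Pf4, Cspg4, Vsig4, Cd81, Olfml3, Trim47, Folr2, Cd36 and C1qc on the higher side. Ifit1bl1 (7.42-fold), Ly6a, Hist1h1e, Chil3, Csnk2a2, Isg15, Mbd2, Ifitm1, Ccl12, Ifit1, Ifit2 and Oasl1 (3.37-fold) were lower. The plateau sum held 2620106 UMIs of 389 cells. With equal weight to each cluster, the medians were 0.20 for tissue macrophage genes, 0.07 for regulatory genes, 0.13 for lysosome genes and -0.06 for the interferon list, none of them outside the random lists. Osteoclast (0.78), cell cycle (0.76) and hypoxia genes (0.25) then lay above and inflammatory genes (-0.15) below them, and nonclassical monocyte, classical monocyte, endothelial and fibroblast genes lost their call. Aqp1 then had a log2 ratio of -0.00092. Nonclassical monocyte genes (0.70, 13 of 15 higher), dissociation stress genes (0.49, 17 of 22 higher) and platelet genes (4.02, or 2.25 with floors, all 4 members under 30 counts) were also higher. Classical monocyte genes (-0.39), neutrophil genes (-0.54, or -0.21 with floors), endothelial genes (-0.35, or -0.38) and fibroblast genes (-0.02, or 0.63 with floors) were lower than the random lists. No call was made for osteoclast genes (0.92), MHC class II (0.06), inflammatory genes (0.18, or 0.21 with floors), NF-kB feedback (-0.01), immune complex receptors (0.12), cell cycle (0.94, or 1.06), adhesion (0.29), hypoxia (-0.03) and oxidative phosphorylation (0.01), nor for NK cell (0.54, or -0.87 with floors), T cell (1.45, or 1.64), B cell (0.95, or 0.62), mast cell (0.51, or 1.02), dendritic cell (0.08) and erythroid genes (1.64, with no member above the floor).

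From plateau to resolution, the inflammatory programme was at a lower level. Interferon response genes were lower in 25 of 25 members (median -2.17), with Cxcl10 26.9-fold lower (12.95 against 349 CPM) and Isg15 8.21-fold lower (47.8 against 392 CPM). Inflammatory cytokines and chemokines were lower in 15 of 21 (median -0.84). Il1b was 3.22-fold lower (597 against 1925 CPM), Ccl7, a monocyte chemokine, 6.26-fold lower (65.0 against 407 CPM) and the prostaglandin synthase gene Ptgs2 5.84-fold lower (14.3 against 83.6 CPM). Anxa8, an annexin, was 19.8-fold higher at resolution (151 against 7.63 CPM, 12.8 to 32.4) and Retnla 18.8-fold higher (165 against 8.78 CPM, 12.5 to 29.7). Tnf was 4.60-fold higher (128 against 27.9 CPM).

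Hspb1, Fabp4, Fxyd2 (6.72-fold, 3325 against 495 CPM), Eno3, Snhg3, Abhd2, Ephx1, Csnk2a2 and Pmepa1 completed the genes higher at resolution. Timp1 (47.6-fold), Dmkn, Ifitm1, Ifit2, Il1rn, Ifit1, Fcgr1, Rsad2, Mmp19 and Lmnb1 (7.67-fold) completed those lower. Tissue macrophage genes (median 0.42, 13 of 18 higher) and nonclassical monocyte genes (1.18, 14 of 15 higher) were higher. Osteoclast genes (-2), classical monocyte genes (-1.44), neutrophil genes (-0.98, or -0.82 with floors), fibroblast genes (-0.90, or -1.41), cell cycle genes (-0.63, or -0.65), lysosome genes (-0.37), hypoxia genes (-0.34), dendritic cell genes (-0.32, or -0.37) and mast cell genes (-2.08, or -2.10) were lower. With equal weight to each cluster 2 calls reversed: tissue macrophage genes (-0.34) lay below and neutrophil genes (0.42) above the random lists. Interferon (0.11), nonclassical monocyte, lysosome, fibroblast and dendritic cell genes lost their call. B cell genes (0.83) then lay above, and NF-kB feedback (-0.30), immune complex receptor (-0.34) and regulatory genes (-0.27) below. No call was made for MHC class II (-0.31), NF-kB feedback (0.11), immune complex receptors (-0.25), regulatory (0.04, or 0.10 with floors), adhesion (0.13), dissociation stress (0.15) and oxidative phosphorylation genes (-0.12). Nor was there one for NK cell (-0.16, or -0.71), T cell (-1, or -0.74), B cell (0.16, or -0.11), erythroid (0.32, or 0.57), endothelial (-0.16, or 0.34) and platelet genes (-0.90, or 0.68), where the floors moved the sign of several.

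Resolution against baseline asks what differed between the joint after arthritis and the joint before it. Spp1, which encodes the matrix protein osteopontin, was 27.7-fold higher at resolution (503 against 18.2 CPM, 23.4 to 33.0), and Ctsk 13.4-fold higher (238 against 17.8 CPM, 11.3 to 16). In B-like, NK-like and mast-like cells at resolution Spp1 had 0 counts and Ctsk 7.503 CPM, at a median depth of 2325 UMIs against 4346 in the class. Regulatory and repair genes were higher in 17 of 22 members (median 0.74, or 0.80 with floors). Anxa1, a mediator that limits leukocyte influx, was 1.94-fold higher (1007 against 519 CPM), and Tgfbi, a matrix protein induced by TGF-beta, 1.86-fold higher (1047 against 563 CPM). Hypoxia and glycolysis genes were higher in 13 of 17 (median 0.46), with Bnip3, a mitochondrial hypoxia gene, 2.45-fold higher. Tissue macrophage genes were higher in 13 of 18 (0.38), with C1qb 2.24-fold higher (2244 against 1003 CPM) and Apoe, a lipid carrier, 1.99-fold lower (1065 against 2115 CPM).

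Anxa8, AA467197, Pdpn and Cd72 were also higher, between 5.72-fold and 4.95-fold. S100a9 (5.71-fold, 17.6 against 100.4 CPM), Cd177, Cxcl10, S100a8 and Slc7a11 (3.47-fold) were lower. Interferon response genes were lower than at baseline in 25 of 25 members (median -1.32), among them Ifit2 5.73-fold. Neutrophil genes were lower in 14 of 14 (median -2.11, or -1.87 with floors) beside a neutrophil-like share of 5.44% at baseline and 0.152% at resolution. With equal weight to each cluster 3 calls reversed: interferon (0.16) and inflammatory genes (0.22) lay above the random lists and tissue macrophage genes (-0.31) below. Regulatory (0.12) and neutrophil genes (-1.72) kept their call, and nonclassical monocyte, cell cycle, adhesion, endothelial and dendritic cell genes lost it. MHC class II (0.48), NF-kB feedback (0.40), fibroblast (0.41) and dissociation stress genes (0.13) then lay above the random lists. Osteoclast genes were higher (1.26, 3 of 5 members). Classical monocyte (-1.38), endothelial (-0.95, or -0.19 with floors), dendritic cell (-0.53, or -0.65), nonclassical monocyte (-0.47), inflammatory (-0.21, or -0.19), adhesion (-0.19) and cell cycle genes (-0.14, or -0.04) were lower. No call was made for MHC class II (0.05), NF-kB feedback (0.03), immune complex receptors (0.06), lysosome (-0.0090), dissociation stress (0.10), oxidative phosphorylation genes (0.01). Nor was there one for NK cell (-0.95, or 0.35 with floors), T cell (-0.42, or 0.0043), B cell (0.72, or 0.05), erythroid (0.03, or 0.52), fibroblast (0.19, or 0.33), mast cell (-0.46, or -1.65) and platelet genes (0.19 either way).

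The sorting markers' own genes were present at all stages in the class. Ptprc, the gene of CD45, had 729, 678, 617 and 530.1 CPM from baseline to resolution and Itgam, the gene of CD11b, 325, 330.0, 348 and 339 CPM. Of genes of excluded markers, H2-Ab1 (MHC class II) had 359, 580 (579.9), 572 and 514 CPM, Ly6c2 431, 779, 417 and 153 CPM, Cd177 87.7, 39.1, 33.6 and 17.1 CPM, and Fcgr1 58.9, 446, 244 and 26.4 CPM. Ly6g had 1, 0, 0 and 0 counts and Siglecf 1, 1, 1 and 0.

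**Figure D2:**
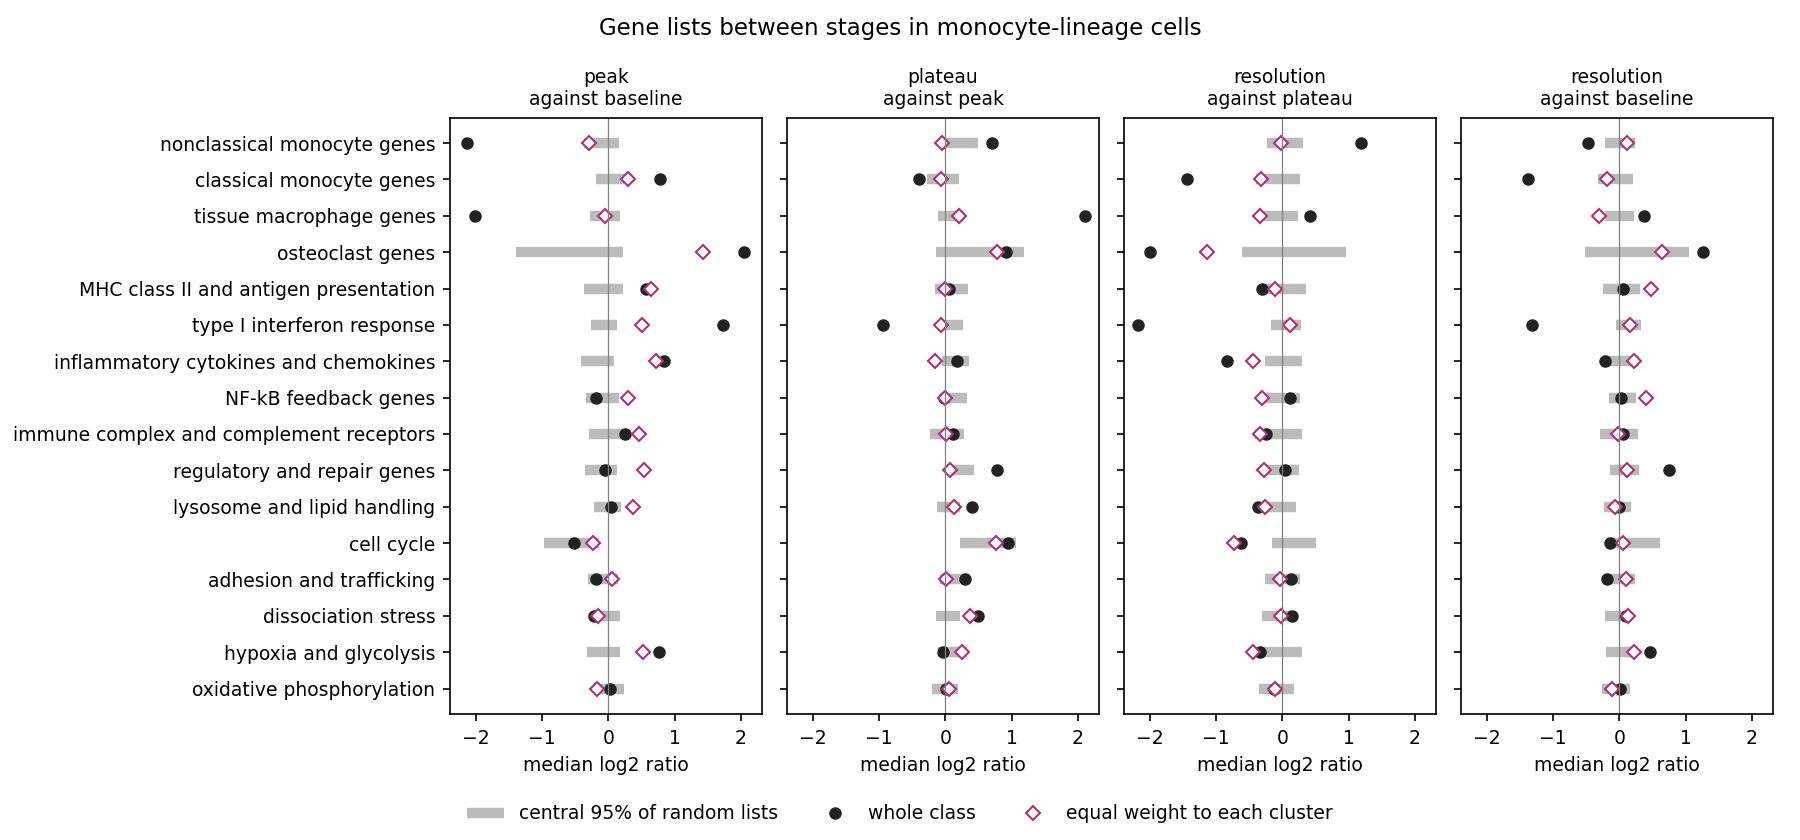
Median log2 ratio (horizontal axis) of 16 gene lists in the 4 stage contrasts, over the central 95% of random lists (grey bars). Dots are the whole monocyte-lineage class, and diamonds give equal weight to each cluster with at least 20 cells in both libraries. The interferon median was 1.73 at peak against baseline and -2.17 at resolution against plateau for the whole class, and 0.51 and 0.11 with equal weight to each cluster.

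Surface proteins of the class were compared between stages as mean antibody UMIs per cell. Ly6C, the marker of classical monocytes that the sort excluded, had 449 UMIs at baseline (447 to 450.3) and 32.1 at peak (31.9 to 32.4). It had 16.3 at plateau and 5.27 at resolution (5.19 to 5.35). Over all retained cells the Ly6C means were 529.8, 33.04, 12.43 and 4.397, so the fall was not particular to the class. Ly6c2 RNA of the class, given above, was instead higher at peak than at baseline. With 1 library per stage, a difference between libraries in this antibody cannot be told apart from a change on the cells. CD14, the lipopolysaccharide co-receptor, was 8.16-fold higher at peak than at baseline (16.4 against 2.01) and 7.89-fold lower at resolution than at plateau (2.69 against 21.2). FrB, the folate receptor of resident macrophages, was 3.35-fold higher at plateau than at peak (23.6 against 7.05), as was the inhibitory receptor CD172a, 8.43-fold (10.8 against 1.28). CD54, an adhesion molecule of activated cells, was 3.96-fold lower at resolution than at plateau (6.64 against 26.3), and Mac-2, a galectin, 3.47-fold lower (7.00 against 24.3). Against baseline, resolution had 14.8-fold lower CD31, 10.8-fold lower CD36, 10.1-fold lower CD90.2 and 5.47-fold lower CD11a, an integrin of circulating leukocytes (26.5 against 145). All antibodies together had 1691, 1021, 773.6 and 472.6 UMIs per cell of the class from baseline to resolution, so as shares of all antibody UMIs every log2 ratio lies higher, by 0.73 for peak against baseline, 0.40 for plateau against peak, 0.71 for resolution against plateau and 1.84 for resolution against baseline. On that scale CD14 stood at -2.27 instead of -2.98 at resolution against plateau. At resolution against baseline Ly6C stood at -4.57 instead of -6.41, CD31 at -2.05 instead of -3.89, CD36 at -1.59 instead of -3.43, CD90.2 at -1.50 instead of -3.34 and CD11a at -0.61 instead of -2.45. The centred log ratio per cell, a natural log of UMIs plus 1 and so another scale, gave smaller differences of the same sign for all named antibodies, such as -0.825 for Ly6C and -1.02 for CD253 at peak against baseline.

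Peak also differed from baseline in CD253, CD36, CD172a, CD31, CD4 and CD90.2, which were 12.7-fold to 5.2-fold lower. Plateau had lower CD124, CD204, CD64, CD11a, CD31 and CD90.2 than peak (3.58-fold to 2.19-fold) and 2.59-fold higher MERTK. From plateau to resolution CD4, CD253, CD8a and CD193 were higher (5.72-fold to 3.13-fold), and CD317 and CD71 lower (4.51-fold and 3.79-fold). Ly108, CD317 and CD102 were also lower at resolution than at baseline (7.74-fold to 4.53-fold, or a log2 ratio of -0.34 for CD102 as a share). The antibody against CD3, which these cells should lack, had 1.26, 0.262, 0.198 and 0.383 UMIs per cell. CD204 at baseline (0.345, against 2.06 at peak), CD138 at peak and resolution (0.161 and 0.359, against 1.81 at baseline) and CD124 at resolution (0.186, against 0.882 at plateau and 1.78 at baseline) lay below it, so no fold is given for them. CD11b, present on all sorted cells, had 461, 328, 237 and 154 UMIs.

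**Figure D3:**
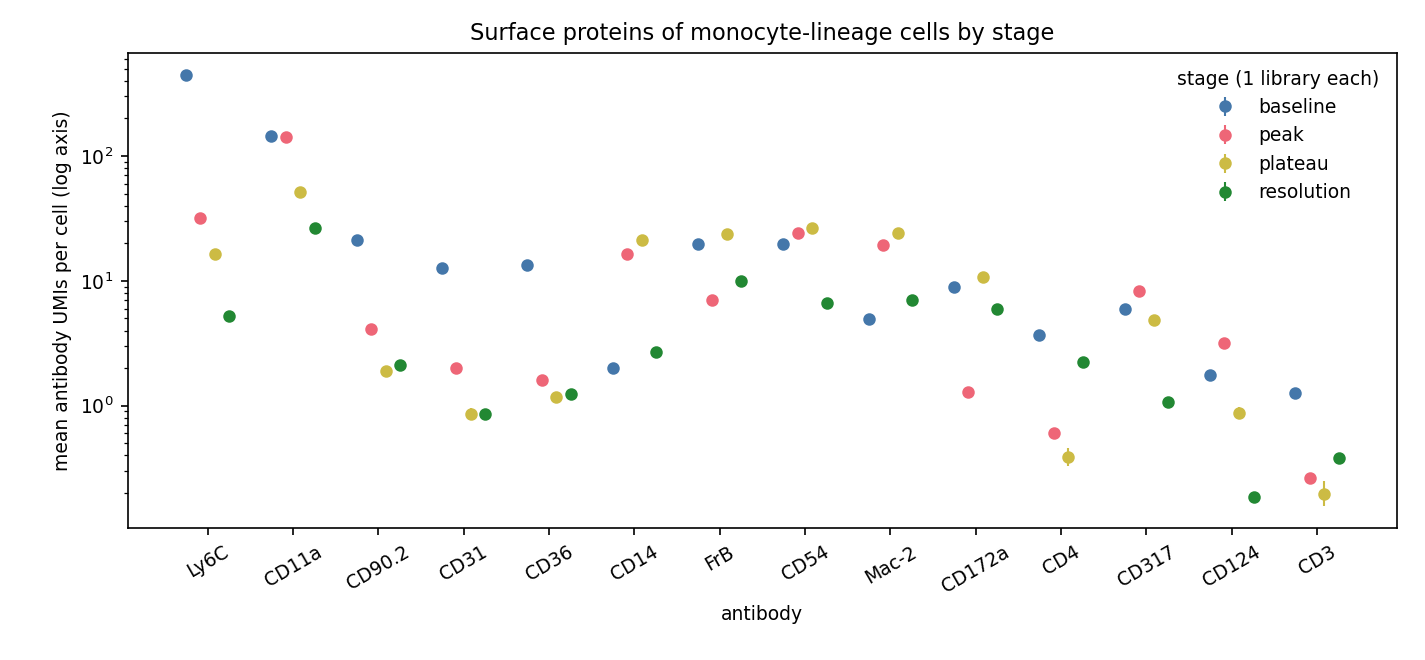
Mean antibody UMIs per cell (vertical log axis) in monocyte-lineage cells at the 4 stages, with 95% Poisson intervals, for 13 named antibodies and for CD3 as background. Ly6C went from 449 at baseline to 5.27 at resolution, and CD14 stood at 16.4 at peak and 21.2 at plateau. Over all retained cells, which are not drawn, Ly6C had 529.8 at baseline and 4.397 at resolution.

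The CD45 antibodies show how much of each population came from donor marrow. Among assigned cells of all types, CD45.1 cells were 83.1% at baseline (80.6 to 85.4), 94.0% at peak (93.3 to 94.6), 79.8% at plateau (78.0 to 81.5) and 87.4% at resolution (86.4 to 88.4). Under the fixed rule of 1 log2 unit the shares were 81.2%, 96.2%, 90.9% and 81.7%, so the order of plateau and resolution depends on the rule. Cells of cluster 3, named nonclassical monocyte-like at this clustering, were almost all of donor origin, with 99.5% CD45.1 at baseline (98.0 to 99.9), 96.7% at peak (92.9 to 98.8), 100% at plateau (92.6 to 100) and 656 of 673 assigned cells at resolution (96.0 to 98.5%). Macrophage-like cells of cluster 11, led by Vsig4, Lyve1 and Timd4, were of recipient origin: none of 89, 32 and 38 assigned cells were CD45.1 at baseline, peak and plateau, which allows up to 3.37%, 9.38% and 7.89%, and 10.3% (6.41 to 15.5) were at resolution. Macrophage-like cells of cluster 2, led by Aqp1 and Fxyd2, were 40.3% CD45.1 at baseline (28.5 to 53.0), 9 of 38 cells at peak (11.4 to 40.2%), 42.6% at plateau (29.2 to 56.8) and 83.5% at resolution (81.2 to 85.6). Osteoclast-like cells were 76.8% (70.4 to 82.5), 81.1% (76.1 to 85.4) and 92.9% (76.5 to 99.1) CD45.1 at peak, plateau and resolution, and the unnamed Spp1-led cluster 4 was 96.4% at peak (94.1 to 98) and 96.2% at plateau (94 to 97.8). Under the fixed rules of 1 and 2 log2 units the share of cluster 2 was 39.4% and 36.5% at baseline, 28.9% and 28.1% at peak, 53% and 51.6% at plateau and 77.3% and 73.3% at resolution. That of cluster 11 was 5.13% and 2.78% at plateau and 7% and 3.96% at resolution, that of cluster 3 was 93.3% and 94.8% at resolution, and that of osteoclast-like cells was 80.5% and 81.5% at peak and 86.8% and 87.2% at plateau.

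Within libraries, the CD45.1 share of cluster 11 was 87.0 points below that of the other cells on average (81.1 to 94.6 points below), and that of cluster 2 was 40.1 points below (5.46 to 70.8 points below), both lower in 4 of 4 libraries. That of cluster 3 was 15.4 points above (2.77 to 25.8), higher in 4 of 4. In each case the exact two-sided sign-flip permutation test gave 2 of 16 sign patterns as extreme, the fewest that 4 libraries allow, so no cluster could pass a level of 0.05. Only these 3 clusters had enough cells in all 4 libraries.

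**Figure D4:**
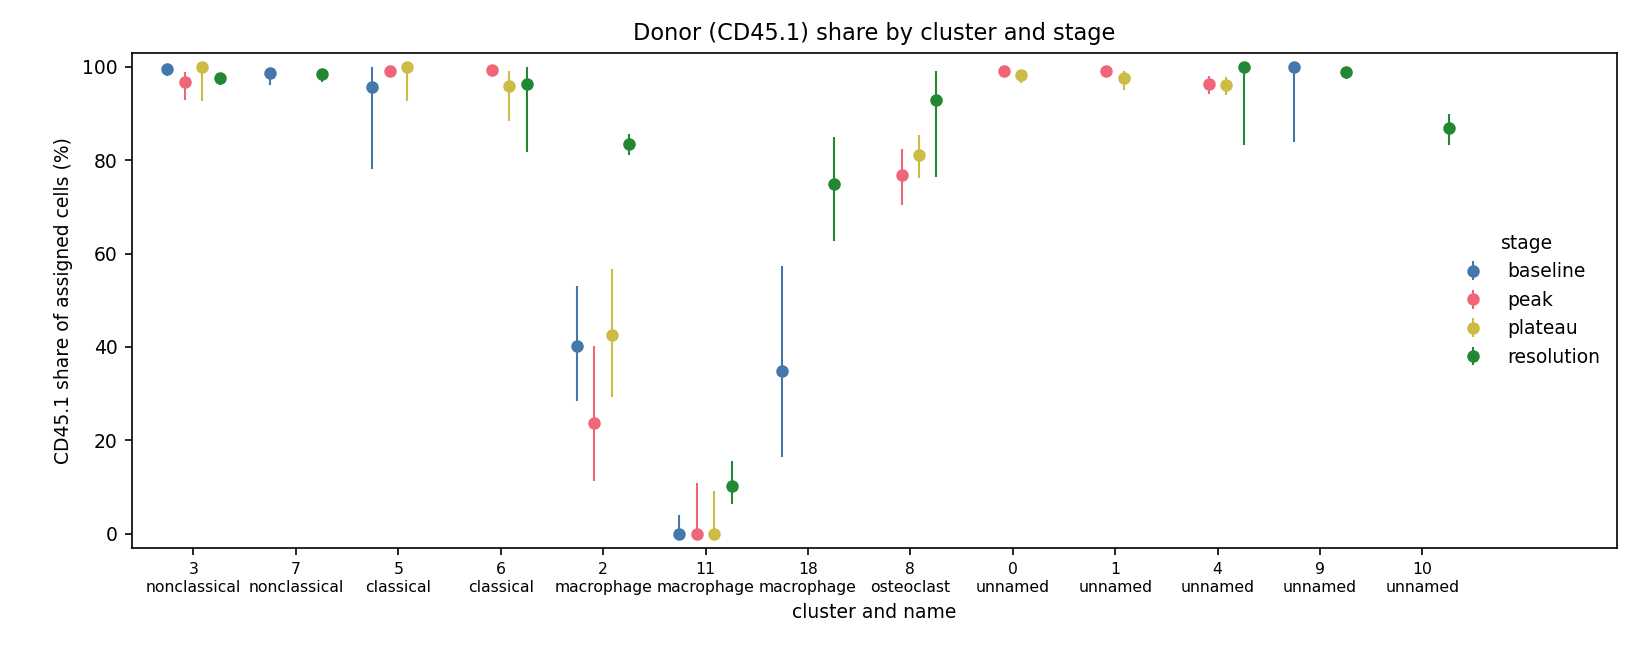
Share of CD45.1 (donor) cells among assigned cells (%, vertical axis) by cluster and stage, with exact 95% binomial intervals, for clusters with at least 20 assigned cells. Cluster 3 lay at 96.7% or above at every stage, cluster 11 at 10.3% or below, and cluster 2 at 42.6% or below before resolution and 83.5% at resolution.

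RNA of CD45.1 and CD45.2 cells of the monocyte-lineage class was compared within libraries, to ask how cells of donor origin differ from those of recipient origin. CD45.2 marks recipient origin and not earlier residence in the joint. At peak, at least 6, 9 and 5 CD45.2 cells lay in the monocyte-like clusters 3, 5 and 6. Genes known from circulating monocytes were among those higher in CD45.1 cells and genes of resident macrophages among those higher in CD45.2 cells, although camera with an estimated correlation called neither the classical monocyte nor the tissue macrophage list (limma adjusted p = 0.319 for both). Plac8, a gene of blood myeloid cells, was higher in CD45.1 cells by 4.07 ± 0.54 on the log2 scale (SE, 4 libraries, edgeR adjusted p = 0.00178), Pglyrp1, an antibacterial granule protein, by 3.98 ± 0.45 (0.00115) and Ly6c2 by 3.55 ± 0.48 (0.00192). Timd4, a receptor for dying cells, differed by -7.66 ± 0.37 (0.000101), Vsig4 by -8.46 ± 1.15 (0.00197), the hyaluronan receptor gene Lyve1 by -6.47 ± 1.26 (0.00644) and the arginine transporter gene Slc7a2 by -5.93 ± 0.36 (0.000159), and thus were higher in CD45.2 cells. Each of these had the same sign in 4 of 4 libraries.

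Of 8895 genes tested, 1603 were higher in CD45.1 and 1459 in CD45.2 cells, and 2871 of these 3062 had the same sign in all 4 libraries. The named genes higher in CD45.1 cells also include Serpinb2, Slamf8, Lcn2, Skint3, Ace, Grk3, Sorl1, Cd177, Dpp4, Padi4, Ms4a4b, Bcl11a and Plcb1. Several rest on few UMIs in the CD45.2 sums, such as Serpinb2 with 2, 1, 0 and 0 and Lcn2 with 3, 0, 0 and 0. Pcolce2, Tcim, Amotl1, Mxra8, Fermt2, Ccn1, Tcaf1 and S100b were higher in CD45.2 cells, by log2 differences of -7.17 to -5.54. Sema6a and Tshz3 had no UMIs in any CD45.1 sum, against 21, 10, 3 and 20 and 13, 6, 8 and 43 in the CD45.2 sums from baseline to resolution, and Apobec2 had 1 CD45.1 UMI in all. Of the sorting genes, Ptprc was higher in CD45.1 cells by 1.42 ± 0.22, H2-Ab1 by 2.12 ± 0.30 and Fcgr1 by 1.86 ± 0.40, while Itgam did not pass (-0.36 ± 0.15, edgeR adjusted p = 0.105).

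With no normalization factors the counts were 1028 and 2100, since the median of all tested genes then moved from 0.010 to -0.24. Without the replicate block for the library they were 1132 and 1007, without the baseline library 1141 and 899, and without the peak library 1160 and 908. When both origins were given the same number of cells from each cluster in each library, 12 genes were higher in CD45.1 and 17 in CD45.2 cells of 4232 tested, and 27 of these 29 were among the 3062. Cluster 2 gave 27 of 41, 9 of 36, 23 of 27 and 185 of 248 matched cells per origin from baseline to resolution, so except at peak these results stand mostly for cluster 2. In cluster 2 alone, with all of its cells in the 3 libraries that had enough, 30 and 35 genes passed (22 and 30 under fixed rule 1). The 29 genes include Fermt2, an adaptor of integrins (-3.74, edgeR adjusted p = 2.0e-05), Retnla (-2.10, 0.0134) and the scavenger receptor gene Cd163 (-2.02, 0.0146) on the CD45.2 side, and Ccl4, an inflammatory chemokine (2.08, 0.00217), Cx3cr1, the fractalkine receptor gene (1.21, 0.0246), and Icam1 (1.39, 0.0220) on the CD45.1 side. With matched cells and fixed rule 1, Retnla (-1.35, edgeR adjusted p = 0.0589) and Cx3cr1 did not pass, while Fermt2, Cd163, Ccl4 and Icam1 did.

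Among the fixed lists, 23 of 24 tested interferon response genes rose in CD45.1 over CD45.2 cells and none fell (24 adjusted over the list alone), with Ifit3b at 3.75 ± 0.56 and Cxcl10 at 3.84 ± 0.75. Genes of MHC class II rose in 8 of 12 (8 adjusted over the list alone), with Cd74, the class II chaperone, at 2.87 ± 0.48. Nonclassical monocyte genes rose in 12 of 14 (13), classical monocyte genes in 9 of 12 with 2 falling (9 and 2), and neutrophil genes in 7 of 8 (7). Tissue macrophage genes fell in 16 of 18 with 2 rising (16 and 2), as with C1qb at -2.98 ± 0.65. Regulatory and repair genes fell in 12 of 19 with 4 rising (12 and 4), among them Cd163 at -4.64 ± 0.51 and Retnla at -4.54 ± 0.53. Adhesion and trafficking genes rose in 9 of 18 with 2 falling (9 and 2), with the integrin genes Itgal at 3.88 ± 0.53 and Itgb7 at 3.45 ± 0.32, and dendritic cell genes rose in 5 of 9 (5). NF-kB feedback genes rose in 8 of 17 with 2 falling (10 and 4), with Traf1 at 2.71 ± 0.35.

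Camera with its preset correlation called these 10 lists, but with an estimated correlation none of the 18 lists tested passed: the limma adjusted p was 0.319 for the interferon, MHC class II, classical monocyte, tissue macrophage, neutrophil, dendritic cell and NF-kB lists. It was 0.351 for the nonclassical monocyte, regulatory and adhesion lists. Inflammatory genes rose in 5 and fell in 5 of 18 (5 and 6 adjusted over the list alone), with Il1b at 3.12 ± 0.52 and Cxcl2 at -0.77 ± 0.22. Immune complex receptors rose in 4 and fell in 2 of 11 (4 and 2), lysosome genes rose in 6 and fell in 6 of 20 (6 and 7), and cell cycle genes rose in 1 and fell in 2 of 6 (1 and 3). Dissociation stress genes rose in 4 and fell in 9 of 22 (6 and 9), with a median of 0.22 while camera and fry pointed down. Hypoxia genes rose in 5 of 16 (3), oxidative phosphorylation genes in 1 of 19 (0) and fibroblast genes in 1 of 3 (1). With cells matched by cluster, none of 7 interferon genes passed (median 0.01) and 3 of 16 tissue macrophage genes fell (median -0.38). Of 10 MHC class II genes 1 rose (6 adjusted over the list alone, median 0.95), but their folds stayed large: H2-Ab1 stood at 1.63 ± 0.39, H2-Aa at 1.87 ± 0.40 and Cd74 at 1.48 ± 0.33, against 2.12 ± 0.30, 2.82 ± 0.39 and 2.87 ± 0.48 as found. With matched cells and fixed rule 1, 5 of 10 rose, among them H2-Ab1 at 1.62 ± 0.32.

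Surface proteins differed between the origins in the same libraries. Of 86 antibodies tested, 12 were higher on CD45.1 and 11 on CD45.2 cells. Tim4, the protein of Timd4, differed by -5.17 ± 0.45 on the log2 scale (SE, 4 libraries, edgeR adjusted p = 8.8e-06), CD163 by -4.59 ± 0.48 (3.1e-05) and FrB by -3.64 ± 0.47 (0.000167), all higher on CD45.2 cells in 4 of 4 libraries. CD11a was higher on CD45.1 cells by 3.98 ± 0.58 (0.000442) and Ly6C by 3.50 ± 0.64 (0.00156), also in 4 of 4. CD61, CD102, CD36, CD31, CD43, CD11c, CXCR4, CX3CR1 and I-A/I-E were among those higher on CD45.1 cells as well, and CD107a, CD71, MERTK, CD169, CD55, CD204, CD68 and CD80 on CD45.2 cells, where CD68 was not read at baseline. The CD3 background set no limit in this test, so antibodies with few UMIs per cell may lie at background on either origin. Cd36 RNA went the other way from its protein (2.93 ± 0.51 for the antibody), at -3.02 ± 0.71 (edgeR adjusted p = 0.0132, 4 of 4 libraries). With cells matched by cluster 3 remained, Tim4 (-4.02), CD163 (-2.50) and I-A/I-E (2.31). Of those that missed the threshold then, CD55 (-1.34 ± 0.30 before and -1.09 ± 0.38 after), CXCR4 (0.83 ± 0.26 and 1.02 ± 0.39) and CX3CR1 (1.10 ± 0.32 and 0.89 ± 0.32) stood at about the same fold, while CD11a (3.98 ± 0.58 and 1.13 ± 0.37) and FrB (-3.64 ± 0.47 and -0.84 ± 0.30) stood nearer 0. None of these folds was set against the CD3 background. Without the peak library 0 were higher on CD45.1 and 2 on CD45.2 cells in edgeR (25 at an unadjusted p under 0.05), and without the replicate block 6 and 5.

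**Figure D5:**
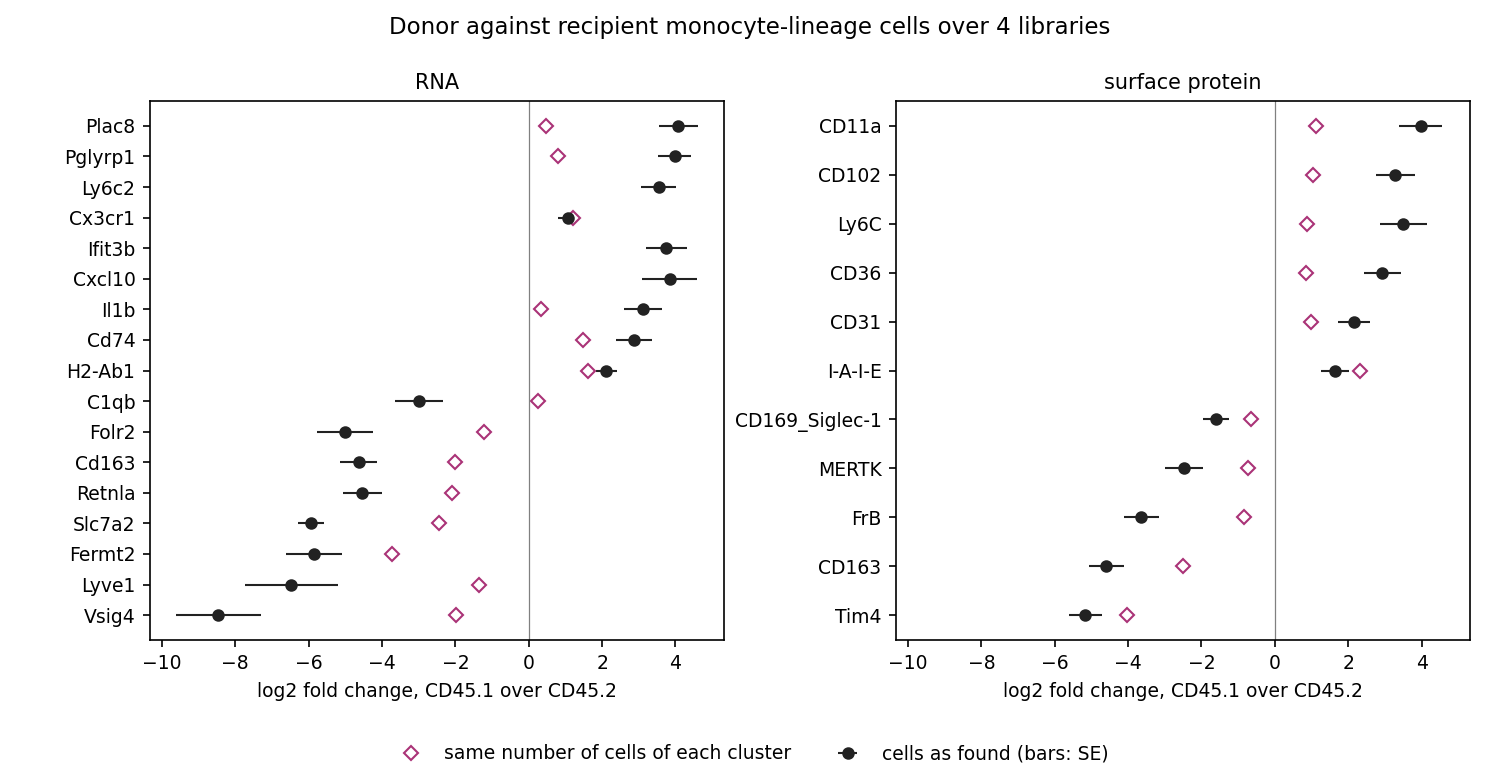
Log2 fold difference of CD45.1 over CD45.2 cells (horizontal axis) with its SE for 17 genes and 11 antibodies in 4 libraries, as found (dots) and with cells matched by cluster (diamonds, where tested). Vsig4 lay at -8.46, the Tim4 protein at -5.17 and Plac8 at 4.07.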

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

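Of the tests below, those on the cell mix and on the splits were chosen after the result was seen, as were the 3 on cluster 2, while those on strain DNA and on osteoclast doublets were written before.

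The number of genes called between CD45.1 and CD45.2 cells fell with matching, as a different cell mix of the origins would give. With the same number of cells of each cluster 29 genes passed. As few cells drawn without regard to cluster gave a mean of 1075 over 10 draws (856 to 1269). The clusters were made from the same RNA, so matching also removes origin differences that place cells in different clusters. The fall therefore cannot tell a different mix from an effect of origin on expression. Matching took Plac8 from 4.07 ± 0.54 to 0.47 ± 0.20 but H2-Ab1 only from 2.12 ± 0.30 to 1.63 ± 0.39, so the MHC class II difference is not shown to come from the mix, and as the matched cells were mostly of cluster 2 except at peak, origin differences within the other clusters stay open. Strain DNA carried with the CD45.1 allele is excluded as the main cause, as 1.93% of the calls lay within 20 Mb of Ptprc (chromosome 1, 138062859 to 138175756, GRCm38.p6), and 3.45% of the matched calls, that is 1 of 29, although genes this near were called more often than all genes (51.75% against 34.42%), so it could account for some of them. Both sums of a library come from the same animals, so the real split was set against the splits of the 8 sums that part each library, of which there are 8, too few for a share under 0.05. Only 1 of the 8 splits, the real one, gave as many RNA calls (3062, highest other 0) and 1 as many surface protein calls (23, highest other 0). The other splits hold both origins on each side, so the origin difference itself widens their spread. Their lack of calls therefore decides nothing.

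Osteoclast-like cells at peak and plateau (3.69% and 13.7% of cells, and 0.672% at resolution) are, as a group, unlikely to be doublets of other cells. The median ratio of their osteoclast markers to the highest other cluster was 4.47, with Acp5 at 4.61, Ctsk at 4.34 and Dcstamp at 4.06, and a doublet could not exceed its parts. Both CD45 antibodies were found on 3.89% of these cells at plateau (2.19 to 6.33), against 16.5% if all were random pairs, while at peak the 4.11% (1.90 to 7.66) does not differ clearly from the 7.31% of random pairs. The random-pair shares take no account of the minimum of 10 UMIs of each antibody and may lie too high. Among all retained cells the shares were lower, 1.63% at plateau (1.195 to 2.17) and 2.14% at peak (1.785 to 2.54). Doublets among part of the osteoclast-like cells are thus not excluded. Their median was 26610 UMIs, 392% of that of their libraries. Why cells sorted as they were include osteoclast-like cells was not tested.

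The higher CD45.1 share in cluster 2 at resolution could mean that marrow-derived cells entered this macrophage-like group after inflammation. Where the antibody limits were set is excluded as the cause, since the smallest difference from baseline over 3 origin rules was 36.8 points. A weaker CD45.2 antibody signal at resolution cannot be told apart, as the CD45.1 share of cluster 11 was 10.3 points higher than at baseline under the mixture, although 7 and 3.96 points under the fixed rules. Library, animals or the tag in the arthritis titles cannot be told apart from stage either, with 1 library per stage.

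The CD169 antibody had a log2 ratio of CD45.1 over CD45.2 cells of 0.052 at resolution and of -3.08, -2.65 and -1.68 at the earlier stages. The CX3CR1 antibody had -0.45 at baseline and 1.19, 1.28 and 1.39 at the later stages. Neither difference between stages was tested, and the levels behind these ratios were not set against the CD3 background. Fibroblast-like cells, outside a CD45 sort, were 4.32%, 2.61%, 5.31% and 4.88% of cells from baseline to resolution, and why they passed the sort was not tested.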

How the results depend on the processing

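Settings are given where they moved a result, and the cause was not tested. All shares are percentages, list values are median log2 ratios, and pairs of counts give CD45.1 before CD45.2. Settings tried on main values left 279 the same and moved 63.

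At clustering resolution 1.2 the monocyte-lineage share was 48.1, 28.9, 11 and 49.4 from baseline to resolution, and without the 6 percent of cells with the highest doublet scores it was 66.5 at resolution. The CD45.1 share with origin by fixed rule 1 was 96.2 at peak, 90.9 at plateau and 81.7 at resolution, and by fixed rule 2 it was 96.9, 93 and 80.6. In the monocyte-lineage class only it was 94.9, 70.9 and 84.5. Without cells with both CD45 antibodies it was 94.9 at peak, and with at least 500 genes per cell 82.4 at plateau. At resolution 0.4, 1 cluster had a lower CD45.1 share in 4 libraries.

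With members with at least 10 CPM, 5 lists were higher and 5 lower at peak against baseline, 3 were lower at plateau against peak and 6 lower at resolution against plateau, and cell cycle genes stood at 0.045 at resolution against baseline.

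With all retained cells, 8 lists were lower at peak against baseline, 12 lower at plateau against peak, 10 higher and 7 lower at resolution against plateau, and 7 higher at resolution against baseline. At peak against baseline mast cell genes then stood at -0.13, Igfbp6 at -0.46 and Sparc at 0.40. At plateau against peak nonclassical monocyte genes stood at -0.61, dissociation stress genes at -0.030 and fibroblast genes at 0.85. At resolution against plateau neutrophil genes stood at 0.36, mast cell genes at 2.08 and dendritic cell genes at 1.05. At resolution against baseline inflammatory genes stood at 0.50, endothelial genes at 0.82 and dendritic cell genes at 0.44. Between the origins 804 and 478 genes and 7 and 5 antibodies passed, with Lcn2 at -1.24, Cxcl2 at 1.07, S100a8 at -0.71 and Prg4 at -2.66.

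With cells thinned to 2000 UMIs, 5 lists were lower at peak against baseline, 3 lower at plateau against peak and 7 lower at resolution against plateau. At plateau against peak fibroblast genes then stood at 0.36 and endothelial genes at 0.64. Fibroblast genes there stood at 0.92 with 5 counts added and at 0.51 without the 6 percent of cells with the highest doublet scores.

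With equal weight to each cluster, 1 list was lower at peak against baseline, 2 lower at plateau against peak, and 9 higher and 3 lower at resolution against baseline. At plateau against peak nonclassical monocyte genes stood at -0.047 and Aqp1 at -0.00092. At resolution against plateau nonclassical monocyte genes stood at -0.019, tissue macrophage genes at -0.34, interferon genes at 0.11, neutrophil genes at 0.42, Ifit2 at 0.28, Ifit1 at 0.77 and Rsad2 at 0.34. At resolution against baseline nonclassical monocyte genes stood at 0.12, tissue macrophage genes at -0.31, interferon genes at 0.16, inflammatory genes at 0.22, cell cycle genes at 0.058, adhesion genes at 0.096 and endothelial genes at 0.036. With equal weight to each cell, 1 list was higher at resolution against plateau and 5 lower at resolution against baseline, with cell cycle genes at 0.054.

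With the class and clusters 0, 1, 4, 9 and 10, 8 lists were lower at plateau against peak, 4 higher at resolution against plateau, and 7 higher and 4 lower at resolution against baseline. Fibroblast genes stood at 0.69 at plateau against peak, cell cycle genes at 0.042 and dendritic cell genes at 0.39 at resolution against plateau, and inflammatory genes at 0.31 at resolution against baseline.

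For antibodies between stages, as shares of all antibody UMIs, Ly6C stood at -3.08, CD253 at -2.94, CD36 at -2.33, CD14 at 3.76, CD172a at -2.08, CD31 at -1.93, CD4 at -1.89 and CD90.2 at -1.65 at peak against baseline. At resolution against plateau CD14 stood at -2.27, CD4 at 3.22, CD253 at 3.14, CD317 at -1.46, CD8a at 2.81, CD54 at -1.27, CD71 at -1.21, Mac-2 at -1.08 and CD193 at 2.35. At resolution against baseline Ly6C stood at -4.57, CD31 at -2.05, CD36 at -1.59, CD90.2 at -1.50, Ly108 at -1.11, CD317 at -0.63, CD11a at -0.61 and CD102 at -0.34. With all retained cells CD14 stood at 4.33 at peak against baseline and -4.12 at resolution against plateau, FrB at 0.58 and MERTK at 0.55 at plateau against peak, CD71 at -3.435 at resolution against plateau and CD90.2 at -2.575 at resolution against baseline.

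With no normalization factors 1028 genes were higher in CD45.1 cells. With the same number of cells of each cluster 12 and 17 genes and 1 and 2 antibodies passed, with Apoc2 at -0.0050, C1qb at 0.27, Ifi30 at -0.075, Osm at -0.21, Cxcl2 at 0.43, Traf1 at -0.014, Tubb5 at 0.010 and the CD68 antibody at 0.31. With that and fixed rule 1, 27 and 32 genes and 1 and 2 antibodies passed, with C1qb at 0.25, Ifi30 at -0.19, Cxcl2 at 0.44, Cycs at -0.16, Ly6c2 at -0.24 and the CD68 antibody at 0.17. As few cells with clusters as found gave a mean of 564 and 510.8 genes.

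Leaving out 1 library gave 899 to 1456 genes higher in CD45.2 cells and 0 to 14 and 2 to 11 antibodies. Without baseline 899 genes were higher in CD45.2 cells, and without peak 908, with 0 and 2 antibodies. With no replicate block 6 and 5 antibodies passed, and with the DESeq2 Wald test 20 were higher on CD45.2 cells. For antibodies, no filter on low counts and the draws of as few cells were not run. Camera with an estimated correlation called 0 lists in either direction.

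For the genes named between the origins, which include some without a call, 1558 entries were the same, 136 weaker, 12 stronger and 16 reversed. Genes without a call counted as the same when they stayed so or changed sign, and a gene not tested under a setting gave no entry. The 1558 is therefore no count of calls that were kept. Antibodies called between the origins kept their call in 314 entries, were weaker in 98 and reversed in 2.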

Other observations

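Named genes within single clusters were chosen after seeing the data, and none of the differences between stages has a test. In cluster 3, named nonclassical monocyte-like at this clustering, Ctsk was 56.3-fold higher at peak than at baseline (112 against 1.99 CPM, 28.8 to 126) and Spp1 19.4-fold higher (51.4 against 2.65 CPM), although Ctsk stood at 242.5 CPM and Spp1 at 1110 in B-like, NK-like, basophil-like and mast-like cells at peak, which leaves free RNA open. In the same cluster the MHC class II genes H2-Eb1, H2-Aa and Cd74 were 4.01-fold, 3.37-fold and 2.96-fold higher at resolution than at baseline.

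In macrophage-like cells of cluster 11, Ctsk was 33.6-fold higher at resolution than at baseline, while Ccl4 was 11.9-fold and Apoe 5.82-fold lower. In macrophage-like cells of cluster 2, Spp1 was 5.93-fold and Il1b 4.30-fold higher at resolution than at baseline, and Cd163 4.25-fold lower. The CD45.1 share of this cluster differed between these stages too (40.3% and 83.5%), and with cells matched by cluster Cd163 was lower in CD45.1 cells (-2.02), so stage and origin are not separated here.

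In cluster 3 the Ly6C antibody had 837 UMIs per cell at baseline and 16.7, 19.2 and 15.2 at the later stages, while Ly6c2 RNA had 599, 357, 589 and 494 CPM. The antibody was 1 of those the sort excluded, and why its level differed from that of the RNA was not tested.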
